A study of Drosophila melanogaster with 6 samples.

How the data were processed

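Total RNA of cultured Drosophila S2 cells was measured on 6 Affymetrix Drosophila Genome 2.0 arrays, 3 of control cells and 3 of cells depleted of ROW by RNA interference. Per the labels' protocols, cells were soaked in double-stranded RNA against ROW for 96 h, and 25 ng of total RNA per sample was amplified isothermally (SPIA) and labelled with biotin. The labels call the control cells wild type and do not say whether they received any double-stranded RNA. They also do not say that the arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

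The deposited values are on the log2 scale, 1 per probe set and array, and were made with RMA per the submitters' processing notes. RMA corrects background, normalizes the arrays by quantiles and summarises the probes of each set. Its version is not given in the sources used here. RMA gives the arrays nearly the same distribution, so a shift shared by most transcripts would not be seen. The amplification and the summary over probes can compress fold changes, so folds are those of the RMA values. The number of arrays limits the precision.

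The table held 18952 probe sets. The 183 Affymetrix control probe sets were left out and 18769 were tested, with no filter on dim probe sets. A symbol was taken from the platform annotation and updated by gene ID against the reference gene table (assembly Release 6 plus ISO1 MT). Of the tested probe sets, 13647 had 1 gene symbol (13544 matched by gene ID), 402 had several and 4720 had none. Genes were named only from probe sets with 1 symbol, which gave 11982 genes. The array annotation's build is not given in the sources used here, so no coordinates are printed and the table served for names, chromosome arms and gene neighbours. The 95th percentile of the 17 tag control probe sets, 3.39 on the log2 scale, served as the background level.

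Groups were compared with limma 3.58.1 (lmFit and eBayes with defaults, two-sided) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets with a threshold of 0.05. SE is the moderated standard error of limma. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, on the brightest probe set of each gene, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Of the 37 lists fixed before the data were examined, 36 were tested. The transposable element list had too few usable matches and is not analysed here. The 6 chromosome arms were tested in the same way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were summarised with pandas 2.3.3.

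The rule for named genes was also fixed before the data were examined. It took the HP1c complex members whatever their values, up to 4 members of each list past the threshold, and the 14 highest and 14 lowest changes. These last came from genes past the threshold whose arrays did not overlap between groups and whose brighter group lay above the median of all probe sets, 1 probe set per gene. Ubqn, a further member of the HP1c complex, is not analysed here because no probe set carried its symbol alone. Genes outside the rule are said to have been chosen after their values were seen.

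The fit was tested on simulated data with the means and spreads of the 18769 probe sets in the comparison of ROW RNAi with control, 200 of them changed. It recovered 56% of those changed by 0.585 on the log2 scale, 70% at 1, 96% at 2 and 98% at 3, with 7 other probe sets called. Camera called a simulated shifted list and 0 of 20 others. Simulated genes varied independently, while the correlation estimated in the oxidative phosphorylation list was 0.45. The simulation therefore does not test list calls that arise from correlated genes. Nor does it test calls of probe sets under variation that many probe sets share across the arrays. Its shift was also larger than the medians of the called lists. Alternatives were another centring or normalization, filters on dim probe sets, other variance models, array weights, the replicate number as a block, leaving out each array, an estimated correlation, the mean of a gene's probe sets and a test against a fold of 1.2. A covariate for a gradient across arrays was added after seeing the data.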

Results

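Expression was compared between 3 control arrays and 3 arrays of S2 cells soaked for 96 h in double-stranded RNA against ROW. S2 is a cultured line of embryonic origin with features of hemocytes, the blood cells of the fly. ROW is a zinc finger protein that associates with the chromatin protein HP1c and with WOC. The comparison asks which transcripts differ once ROW is depleted. Since the labels name no double-stranded RNA for the controls, loss of ROW cannot be told apart from soaking in double-stranded RNA. The array medians lay between 4.88 and 5.04 on the log2 scale, and array pairs correlated across probe sets with r between 0.987 and 0.998 (probe sets are not independent replicates).

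The row transcript fell in all 3 ROW RNAi arrays on each of its 3 probe sets. The brightest fell from 10.5 ± 0.08 to 8.95 ± 0.07 (log2 mean ± SD, n = 3 arrays each), a log2 fold change of −1.58 (SE 0.07, limma adjusted p = 0.0023) that left 33.5% of the control level. On the other row probe sets the log2 fold changes were −2.61 (SE 0.10, adjusted p = 0.0018) and −2.66 (SE 0.09, adjusted p = 0.0017), which left 16.4% and 15.9%. Transcripts of its partners did not pass the test, with woc at −0.04 (SE 0.07, adjusted p = 0.80) and HP1c at 0.02 (SE 0.06, adjusted p = 0.89). The sign of HP1c turned with median centring and without ROW RNAi replicate 3 (both −0.03), and that of woc without control replicate 3 (0.01).

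**Figure D1:**
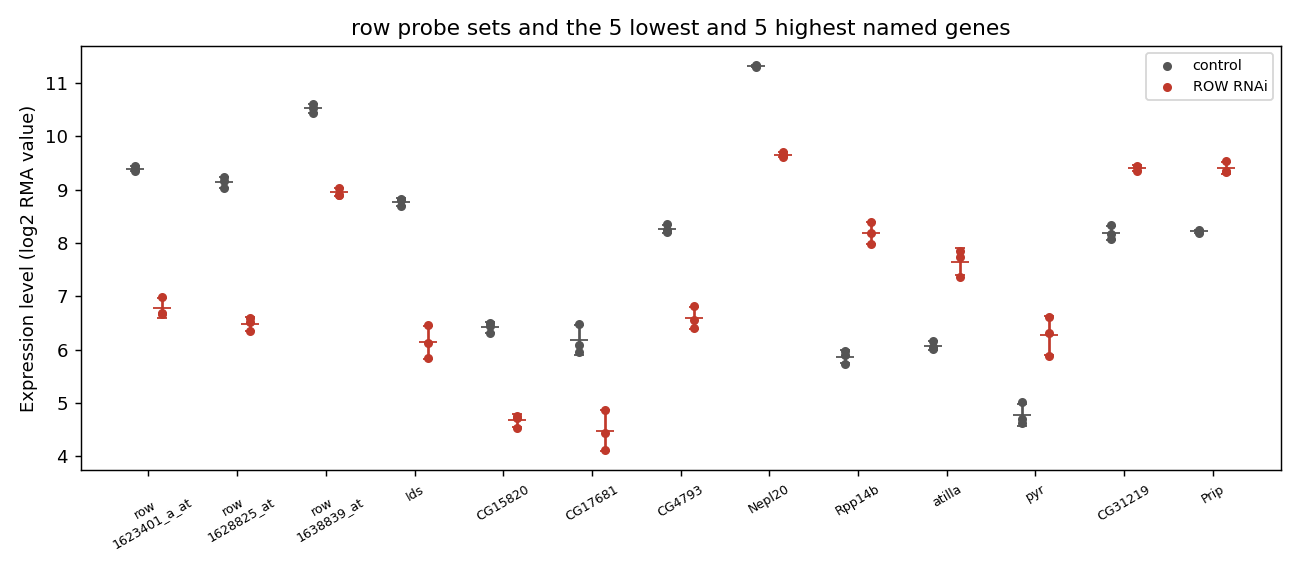
Expression level (log2 RMA value) of the 3 row probe sets and of the 5 lowest and 5 highest named genes; each point is 1 array, grey for control and red for ROW RNAi, and bars give the mean ± SD of 3 arrays. The groups do not overlap for any row probe set, while the other genes were chosen by a rule that required this. The brightest row probe set lies at 10.5 in control and 8.95 in ROW RNAi arrays.

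Ids, which encodes the lysosomal enzyme iduronate 2-sulfatase, fell most among the named genes other than row, by 2.63 on the log2 scale (SE 0.16, adjusted p = 0.0046), from 8.78 to 6.14. Nepl20, a gene of the neprilysin-like metallopeptidases, fell from 11.3 to 9.65 (log2 fold change −1.66, SE 0.05, adjusted p = 0.0014). Also lower were otk, which encodes a receptor tyrosine kinase-like protein (−1.34, SE 0.08), out, which encodes a transporter-like protein (−1.32, SE 0.13), and the fatty acid synthase gene FASN2 (−1.22, SE 0.17). The genes CG15820, CG17681, CG4793, CG15209, CG8157 and CG18094 were also lower, with log2 fold changes of −1.74, −1.69, −1.68, −1.44, −1.30 and −1.28. Other probe sets of CG4793 gave 0.02 and −0.35, and another of CG15820 gave −0.88. The seminal fluid protein gene Sfp26Ad (−1.22, SE 0.07) and Elba2 (−1.45, SE 0.14) were lower as well.

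Rpp14b rose most, by 2.32 on the log2 scale (SE 0.12, adjusted p = 0.0040), a 5.0-fold change from 5.87 to 8.19. Next were atilla, a surface marker of lamellocytes (1.58, SE 0.14, adjusted p = 0.010), and pyr, which encodes a fibroblast growth factor ligand (1.49, SE 0.21, adjusted p = 0.042). The aquaporin gene Prip rose by 1.19 (SE 0.07; another probe set gave 0.45), the serpin gene Spn88Eb by 1.13 (SE 0.11), the TRP channel gene pain by 0.92 (SE 0.09), Esyt2 by 0.87 (SE 0.06) and the scavenger receptor gene Sr-CIV by 0.86 (SE 0.07). The genes CG31219, CG10126, CG18249, CG5397, CG30016 and CG8501 rose by 1.21, 1.12, 1.11, 1.00, 1.00 and 0.89.

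In all, 218 of 18769 probe sets changed at an adjusted p of 0.05 in limma, 76 higher and 142 lower, against 2590 at an unadjusted p under 0.05. Of these, 41 changed at least 2-fold, 11 higher and 30 lower. The 218 covered 193 genes named by 1 symbol, 67 higher and 126 lower. The 3 arrays of each group did not overlap in all 218, and in 21.4% of all tested probe sets, where chance gives 10% on average over the splits of the arrays. Probe sets vary together, so the share of a single split can lie far from 10%. It was not computed for the other splits. The count was 26, 24 and 27 without control replicate 1, 2 or 3, and 64, 517 and 53 without ROW RNAi replicate 1, 2 or 3. It was 107 with median centring, 122 with an unmoderated test, 558 with trend and robust variance, 575 among probe sets above the median mean, and 106 with the gradient covariate. With the replicate number as a block it was 0. Of the 27 named highest and lowest genes other than row, 13, 12 and 14 stayed past the threshold without control replicate 1, 2 or 3, and 20, 27 and 16 without ROW RNAi replicate 1, 2 or 3. With an unmoderated test 17 of them stayed, and with the replicate number as a block 0.

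**Figure D2:**
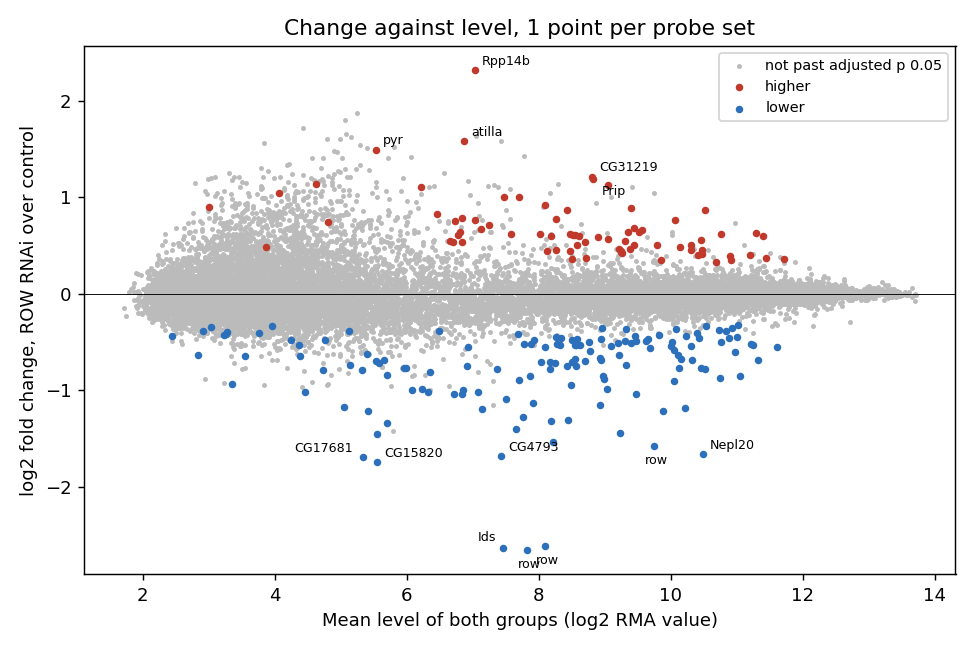
The log2 fold change of ROW RNAi over control against the mean level of both groups (log2 RMA value), with 1 point per probe set; red and blue points passed an adjusted p of 0.05 and grey points did not. Of the coloured points, 76 lie above 0 and 142 below, and Rpp14b is the highest at 2.32.

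Markers of crystal cells and lamellocytes, specialised hemocytes, were shifted upward as a list. Of 14 measured, 2 rose and 3 rose adjusted over the list alone, 12 were above 0 and the median was 0.11 (camera adjusted p = 0.00038; adjusted p = 0.47 with an estimated correlation). The members past the threshold were atilla and the integrin gene ItgaPS4 (0.46, SE 0.07). Plasmatocyte markers were not called as a list (26 measured, adjusted p = 0.93). Of them, Sr-CI, a scavenger receptor gene, rose by 0.62 (SE 0.07) and He, the hemocyte surface gene hemese, fell by 0.69 (SE 0.06), and adjusted over the list alone 1 rose and 2 fell.

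Genes of DNA replication were shifted downward as a list, with 38 of 41 below 0 and a median of −0.07 (camera adjusted p = 0.0043; adjusted p = 0.33 with an estimated correlation). None passed alone, over all probe sets or adjusted over the list alone. The median over all tested probe sets was also below 0, at −0.03, and camera tests a list against the other genes. Lists that were not called had like medians, such as insulator and boundary genes (−0.08) and mitosis (−0.06). The 30 genes of ribosome biogenesis and polymerases I and III had a median of −0.07 and no member past either threshold (adjusted p = 0.045; adjusted p = 0.49 with an estimated correlation). This call was lost without control replicate 1, 2 or 3 (adjusted p = 0.090, 0.068 and 0.14) and without ROW RNAi replicate 2 (0.39). The calls on DNA replication, on crystal cell and lamellocyte markers and on antioxidant genes were kept without each array and with each other scaling. The call on ribosome biogenesis was lost with median centring (adjusted p = 0.076), with array weights (0.096), among probe sets above the median mean (0.055) and with the replicate number as a block (0.19).

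Antioxidant and detoxification genes were shifted upward (40 measured, median 0.04, camera adjusted p = 0.0056; adjusted p = 0.33 with an estimated correlation). None passed over all probe sets, and 6 rose and 1 fell adjusted over the list alone. Upward shifts were also called for oxidative phosphorylation (57 measured, median 0.03, adjusted p = 0.0070; adjusted p = 0.87 with an estimated correlation) and cytosolic ribosomal proteins (39 measured, median 0.02, adjusted p = 0.026; adjusted p = 0.84 with an estimated correlation). In neither did a member pass, over all probe sets or adjusted over the list alone. Camera compares a list with the other genes, and the median over all tested probe sets was −0.03. Upward calls with medians this near 0 are therefore relative to the other genes, and a rise in level is not shown. The cytoskeleton and adhesion list was called upward (40 measured, median 0.03, adjusted p = 0.021; adjusted p = 0.65 with an estimated correlation), while its 1 member past the threshold, the tubulin gene betaTub97EF, fell by 0.63 (SE 0.06). Adjusted over the list alone, 1 rose and 2 fell.

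Immune genes were called upward (37 measured, median 0.03, adjusted p = 0.045; adjusted p = 0.47 with an estimated correlation). Drs, which encodes the antifungal peptide drosomycin, rose by 0.77 (SE 0.06), while GNBP3, a recognition protein for fungal glucans, fell by 0.60 (SE 0.05) and Nazo, an antiviral gene, by 0.47 (SE 0.06). Adjusted over the list alone, 2 rose and 2 fell. With the gradient covariate the adjusted p was 0.20 for the immune list, 0.28 for oxidative phosphorylation, 0.22 for cytoskeleton and adhesion and 0.58 for cytosolic ribosomal proteins. Each of these 4 calls was also lost without 1 array or another: immune without control replicate 2 (0.11) or ROW RNAi replicates 1 (0.16) and 2 (0.12), cytoskeleton without control replicate 2 (0.083) or ROW RNAi replicate 1 (0.11), oxidative phosphorylation without control replicate 3 (0.088) or ROW RNAi replicate 3 (0.53), and ribosomal proteins without control replicates 2 (0.083) and 3 (0.15) or ROW RNAi replicate 3 (0.45). All 4 were lost with median centring (0.076 for immune, oxidative phosphorylation and cytoskeleton, 0.26 for ribosomal proteins), which turned the mean log2 fold change of immune genes, oxidative phosphorylation and ribosomal proteins below 0 (−0.01, −0.01 and −0.02), and with cyclic loess (0.091, 0.17, 0.098 and 0.54 in that order). A further quantile normalization ended the call on ribosomal proteins (0.21) and array weights that on the immune list (0.096). The replicate number as a block ended the calls on ribosomal proteins and on the immune list (0.069 each).

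**Figure D3:**
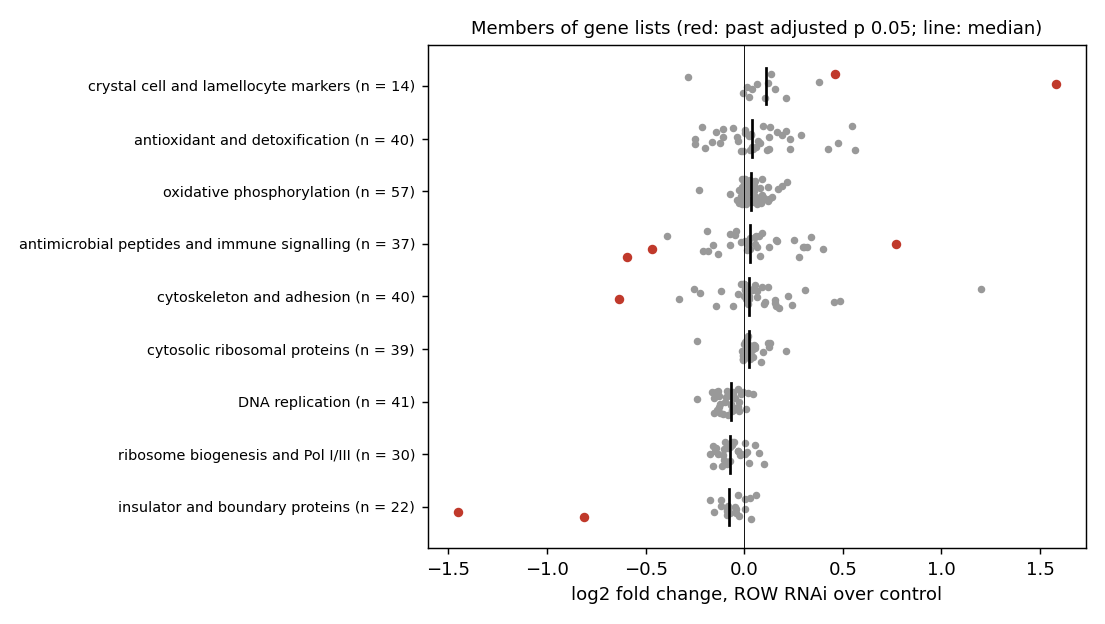
The log2 fold change of each measured member of the 8 lists called by camera and of the insulator list, with 1 point per gene; red points passed an adjusted p of 0.05 and black lines mark medians. The medians of the called lists lie between −0.07 and 0.11, and Elba2 and insv are the lowest insulator members.

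Among 22 insulator and boundary genes, Elba2 and insv, which encode BEN-domain proteins, fell by 1.45 and 0.81 (SE 0.14 and 0.08), and the same number fell adjusted over the list alone. The list as such was not called (adjusted p = 0.081), but was called downward without ROW RNAi replicate 1 (adjusted p = 0.046). Among 26 lipid genes, the perilipin gene Lsd-1 fell by 0.99 (SE 0.07) and wun2, which encodes a lipid phosphatase, rose by 0.65 (SE 0.06), with 2 higher and 2 lower adjusted over the list alone (adjusted p = 0.47 for the list). Among 37 ecdysone genes, nvd, which encodes an enzyme of ecdysone synthesis, fell by 1.04 (SE 0.06), ImpE3 by 0.55 (SE 0.07) and Cth, which encodes cystathionine gamma-lyase, by 0.55 (SE 0.06). Adjusted over the list alone, 1 rose and 3 fell (adjusted p = 0.85). In the small RNA list cuff rose by 0.44 (SE 0.06), with 1 higher and 2 lower adjusted over the list alone among 25 genes (adjusted p = 0.83). Of 23 Notch genes, numb, an inhibitor of Notch, fell by 0.70 (SE 0.08), with 2 lower adjusted over the list alone (adjusted p = 0.23). The HP1c complex list was not called (3 measured, adjusted p = 0.23), with row its 1 member past the threshold on both adjustments. The 28 lists not called had adjusted p-values between 0.064 and 0.96, and 21 of them had no member past the threshold. With 1 array left out, 4 of them were called. Besides the insulator and germline lists these were mitosis, downward without ROW RNAi replicate 1 (adjusted p = 0.019), and mitochondrial ribosomal proteins, upward without control replicate 1 (0.022), ROW RNAi replicate 1 (0.039) or ROW RNAi replicate 2 (0.044). In 11 of the 28 the median, the mean and the test differed in sign, and in 0 of the 8 called lists. By fry, unadjusted p-values were 0.00024 for DNA replication, 0.00074 for ribosome biogenesis, 0.0041 for crystal cell and lamellocyte markers and 0.017 for antioxidant genes. They were 0.064 for immune genes, 0.23 for cytoskeleton, 0.42 for cytosolic ribosomal proteins and 0.49 for oxidative phosphorylation. Lists not called by camera could also have small fry p-values, such as 0.00019 for H2B ubiquitylation and pausing factors and 0.0016 for insulator genes. Fry tests a list against no change, so an offset shared by most genes also enters its p-values.

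Mean levels of neuronal genes were 5.38, 5.27 and 5.29 in the control arrays and 5.65, 5.24 and 5.40 in the ROW RNAi arrays, in replicate order. Those of germline and testis genes were 5.06, 4.88 and 4.95 against 5.33, 4.90 and 5.21. Neither list was called (38 and 34 measured, camera adjusted p = 0.31 and 0.24), though without ROW RNAi replicate 2 the germline list was (adjusted p = 0.045). The first principal component held 66.9% of the variance between arrays, with scores of −3.69, −26.5 and −13.7 in control and 42.7, −19.5 and 20.8 in ROW RNAi arrays.

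**Figure D4:**
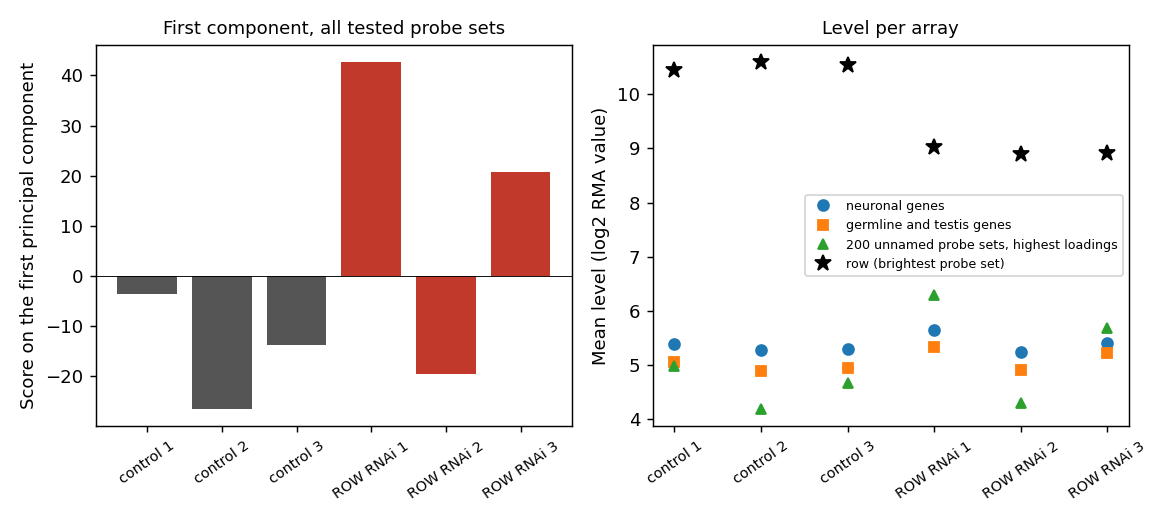
Left, score of each array on the first principal component of all tested probe sets, with bars from 0, grey for control and red for ROW RNAi. Right, mean level per array (log2 RMA value) of neuronal genes, germline and testis genes, the 200 unnamed probe sets with the highest loadings and the brightest row probe set; ROW RNAi replicate 2 scores −19.5, between control replicates 2 and 3, while row is low in it.

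Genes on chromosome 4 were shifted downward, and no other arm was called. The 65 measured genes had a median log2 fold change of −0.11 (camera adjusted p = 0.035; adjusted p = 0.94 with an estimated correlation). Of them 3 fell and 0 rose. These were Zip102B (−0.49, SE 0.06), dpr7 (−0.56, SE 0.07) and RhoGAP102A (−0.47, SE 0.07), named after their values were seen. The other 5 arms had adjusted p-values between 0.84 and 0.91 and medians between −0.04 and −0.02. The call on chromosome 4 was lost without control replicate 3 (adjusted p = 0.24) and without ROW RNAi replicate 2 (0.42). It was also lost with median centring (0.068), with array weights (0.071) and with the replicate number as a block (0.075).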

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

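The tests of RNA degradation, of ROW depletion as the whole cause and of carried DNA or unprocessed transcripts were chosen only after the gradient was seen. In signal outside the comparisons, the 14 hybridization control probe sets averaged 11.4 on ROW RNAi replicate 2, which was 0.55 log2 units above the highest control array (10.8).

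The first pattern is the count of changed probe sets. The real grouping gave 218 and the highest of the other splits gave 0, so 1 of the 10 splits of the 6 arrays reached as many. With 10 splits a share under 0.05 cannot be reached.

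The second pattern is a gradient across the arrays. On the first component of the probe sets with no gene name, ROW RNAi replicates 1 and 3 scored 24.7 and 12.5 and replicate 2 scored −13.7, while the controls scored −1.24, −15.5 and −6.80. Medians of the tag control probe sets were 2.64, 2.84 and 2.82 in control and 2.34, 2.91 and 2.54 in ROW RNAi arrays, in replicate order. They were lowest on ROW RNAi replicates 1 and 3, which had the highest scores, and a link to background signal was not tested. Whether ROW depletion is the whole cause stays open, since the lowest ROW RNAi score minus the highest control score was −12.4 with all arrays and 13.7 without ROW RNAi replicate 2. RNA degradation stays open too, since the 3' minus 5' difference of 5 control probe set pairs differed by 0.039 ± 0.20 (SD) between the arrays with the highest and lowest scores, with members from −0.11 to 0.38. Carried genomic DNA or unprocessed transcripts were not supported and not excluded, since unnamed dim probe sets rose 1.03 times as often as named ones (95% interval 0.88 to 1.21).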

How the results depend on the processing

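The gradient covariate was chosen after seeing the data. For changed probe sets (218), higher (76), lower (142), at least 2-fold (41), called lists (8) and called arms (1), counts that moved by over 1.5 times were as follows. Median centring gave 107, 33 and 74 with 3 lists and 0 arms. Cyclic loess gave 4 lists. Probe sets above the median mean gave 575, 207 and 368, with fewer tested. Trend and robust variance gave 558, 222 and 336. The unmoderated test gave 122, 43, 79 and 26. Array weights gave 0 arms. An estimated correlation gave 0 lists and 0 arms. The gradient covariate gave 106, 39 and 67 with 4 lists. Leaving out 1 array gave 24 to 517 changed, 5 to 259 higher, 19 to 258 lower, 19 to 118 at least 2-fold, 4 to 9 lists and 0 to 1 arms; 517, 259, 258 and 118 came without ROW RNAi replicate 2, and the other arrays gave 24 to 64 changed. Apart from the fewer probe sets tested, the cause was not tested. The row log2 fold change stayed between −2.28 and −1.54.

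With the replicate number as a block, limma called 0 probe sets (0 higher, 0 lower, 0 at least 2-fold; 2924 at an unadjusted p under 0.05), 5 lists and 0 arms, 0 of the 27 named highest and lowest genes passed, and row stood at −1.58 (adjusted p = 0.056; range over the alternatives 1.3e-06 to 0.056). Deviations of same-numbered arrays correlated at 0.48, 0.55 and −0.04 across probe sets. The labels do not say that the numbers mark a shared culture or day, so they were not taken to pair the samples. A shared effect of the numbers is not excluded, since the differences of replicate 1 minus 2 correlated at 0.59 between the groups. Control replicate 3 correlated best with ROW RNAi replicate 1 (0.07). HP1c reversed with median centring (−0.026) and without ROW RNAi replicate 3 (−0.029 to 0.060 without 1 array), and woc without control replicate 3 (−0.084 to 0.0060). Signal limits dim probe sets: 23.4% of values lay at or under the background level.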

Other observations

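The tests of expressed genes lying together and of overlapping or abutting transcripts were chosen after the adjacent pairs were counted, and the genes of the first 2 paragraphs after their values were seen. After ROW RNAi the fructose bisphosphatase gene fbp fell by 0.94 (SE 0.05, limma adjusted p = 0.0043) and the phosphoglucomutase gene Pgm1 by 0.85 (SE 0.07, adjusted p = 0.0090). Cbs, which encodes cystathionine beta-synthase, the enzyme before Cth, fell by 0.53 (SE 0.08, adjusted p = 0.048). Also lower were Nplp1, a neuropeptide precursor gene (−1.17, SE 0.11), Mctp (−1.15, SE 0.10; a dim second probe set gave −0.02) and nolo, whose 3 probe sets gave −0.88, −0.75 and −0.60. No enrichment was tested for these genes.

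The Zasp52 gene, which encodes a protein of the actin cytoskeleton, rose by 0.63 (SE 0.05, adjusted p = 0.0072), the formin gene DAAM by 0.68 (SE 0.08, adjusted p = 0.025), Whamy by 0.51 (SE 0.07), the integrin gene Itgbn by 0.46 (SE 0.05) and Arpc3B, of the Arp2/3 complex, by 0.40 (SE 0.05). The GTP cyclohydrolase gene Pu rose by 0.64 (SE 0.08). Enrichment was not tested for these rising genes either. In the fixed cytoskeleton and adhesion list, called upward by camera, 1 gene rose and 2 fell adjusted over the list alone. The gene mod(mdg4), which makes many isoforms that differ at the 3' end, had 22 probe sets. Of these 1 rose, by 0.51 (SE 0.05, adjusted p = 0.020), and 20 of the other 21 were below 0 with none past the threshold.

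The third pattern is that called genes lay next to each other. In 9 pairs of adjacent genes both changed the same way, all 9 downward, against a median of 1 and an upper bound of 4 for the central 95% of 10000 random draws of genes (one-sided permutation p = 1e-04, the smallest the draws can give), and 2 adjacent pairs changed in opposite directions. Of the 9, 4 came from 2 runs of 3 genes, and the pairs included insv with Elba2, Nepl19 with Nepl20, and dpr7 with RhoGAP102A. Adjacency was taken among the 11888 measured genes on the arms, 186 of them called. Pairs were counted in the main fit only, so their dependence on single arrays and on the processing was not tested. Draws matched on mean level gave a median of 2 (permutation p = 2e-04), which argues against expressed genes lying together as the whole cause, and 4 pairs, 2 of them from 1 run, lay over 1000 bases apart (matched permutation p = 0.0015), which argues against overlapping or abutting transcripts for those 4. Probes shared between neighbouring paralogs may account for some pairs, such as Nepl19 with Nepl20, and stay open because no probe sequences were used here.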
